A study of Mus musculus with 78 samples.

How the data were processed

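Adult mouse retina cells were sorted from 22 transgenic lines, 200 cells per sample after a dissociation of 15 min, and hybridized to Affymetrix Mouse Gene 1.0 ST arrays, 78 in all in 26 sets of 3 biological replicates. The deposited table holds 1 intensity per probe set and array. The submitters' processing notes name RMA in the oligo package, R 2.11.1 and the mouse build mm9, without their settings. The 78 columns share identical sorted values (largest difference 0), as quantile normalization gives. The plan, written before the data were examined, assumed log2 values, but the values run from 0.0238 to 5770 on a linear scale, so log2 was taken of them. The number of arrays limits the precision of every value.

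Of 22347 probe sets 19446 carry 1 gene symbol in the probe table, 735 carry several and 2166 are not listed; the latter kinds were tested only in an alternative and are not named. Where a gene had several probe sets, the one with the highest mean was kept, which left 19301 genes. A gene was tested if the mean of at least 1 of the 26 sets was above 9.01, the median of all values, which kept 15102 genes and left out 4199 as dim. On each array the lowest values stand in descending order of probe set identifier, in a run of 10 or more on 70 of the 78 arrays. These carry no order. The run ends below 1 on 56 arrays, and at 3.99 on the array with the longest run. That value was taken as the floor of every array, so that all are read down to the same level, although on most arrays values just below it are not in a run. Values at or below it make up 10.5% of the values of an array, and 6056 tested genes have at least 1. Differences were computed on the values as deposited and again with values raised to this floor. A difference is given as a bound from the second fit where the fits differ by more than 1.5 times and the arrays of the higher group lie above the floor.

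Linear models were fitted in limma 3.58.1 (R 4.3.3) with moderated statistics and a trend in the prior variance. Class comparisons used the 22 line means (Arc and b2 as the mean of their 3 sets) and set a class against the unweighted mean of the other 5. Comparisons of lines and of repeated sets used all 78 arrays with 1 mean per set. A line was compared with the mean of the other lines of its class, and each driver gene in its own line with the mean of the other 21 lines. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of at least 1 on the log2 scale, within each comparison over all genes tested. The p-values of line and set comparisons measure the spread between the arrays of a set, those of classes the spread between line means. The former do not cover how far a line varies when measured again. The 2nd and unnumbered b2 sets, of the same batch label, differed in 307 genes by that fit. Line contrasts with batch as a term and class contrasts with batch removed left out the d4 and Fbxo32 lines, which have no batch label. Arc 2nd was taken as batch 2 from its number. Only Arc and b2 were measured in more than 1 batch, so the batch term was estimated from their sets alone. A call lost with it may therefore reflect a change between the sets of Arc or b2 that other lines do not share. Replicate numbers were checked as a pairing of arrays across sets: residuals of equal numbers correlated at a mean of 0.000207, so they were not used as pairs.

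Gene lists (42, of which 20 hold cell type markers, 14 functions and 6 retinal diseases) were fixed in the same plan. The 39 with enough tested members were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation. List shifts were adjusted over all lists and comparisons of classes, and of lines, together. Named genes follow a rule also fixed beforehand: the 10 largest positive differences per class among called genes above every line of the other classes. It adds the 10 largest per direction for the pairs of photoreceptor lines and the 5 largest per line among called genes whose arrays do not overlap, the 20 driver genes, and list members as examples or exceptions. Examples from the lists and single transcription factors were picked after their values were seen. Transcription factors were taken by symbol patterns.

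Alternatives covered the filter, normalization, probe set choice, replicate block, batch, each replicate and line left out, and the list correlation. The floor and a fit without the 5 lines whose arrays correlated least (lowest r below 0.8) were added after the data were seen. The fits were tested on simulated data with normal noise, without batches, differences between sets or ordered low values. Of 50 genes changed by 2 log2 units, between 60% and 98% were recovered in 6 comparisons, with 0 to 9 false calls. The measured arrays do differ between sets: repeated sets of 1 line differed in 8 to 314 genes. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in python 3.11.15. Every one of the 78 arrays was used, and raw image files were not analysed here.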

Results

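Cells of the adult mouse retina carrying a red or green fluorescent protein were sorted from 22 transgenic lines, 200 cells per sample, and their RNA was measured on 78 whole-transcript arrays. Each line gave 1 set of 3 biological replicates, except the rod line b2 and the amacrine line Arc, which were measured as 3 sets (9 arrays) each. By the labels the lines fall into 6 classes: 3 photoreceptor lines (15 arrays), 1 horizontal cell line (3), 4 bipolar lines (12), 9 amacrine lines (33), 4 ganglion cell lines (12) and 1 microglia line (3). The labels give batch 1 for 24 arrays, batch 2 for 12, batch 3 for 33 and no batch for 9. Across genes, which are not independent replicates, arrays of a set correlated at a median r of 0.919, with the lowest value of 0.7 in the Crh line, against 0.873 between repeated sets of a line, 0.881 between lines of a class and 0.755 between classes. Differences are given on the log2 scale of intensity. The lowest values of an array carry no order, up to 3.99 on the array where these reach highest, and 3.99 was taken as a floor for all arrays. A gene below it in the compared group is given a lower bound ("at least") where the floor changes its difference by more than 1.5 times. Such bounds hold only if no signal was taken off before the deposit, and values with batch removed or as a term are without the floor. The growth protocol says that mice from 1 supplier carried a recessive mutation causing photoreceptor degeneration before they were backcrossed. All 78 arrays carry the same label of mixed background, so its part in differences of rod and cone transcripts between lines was not tested.

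The first comparison asks which genes set each of the 6 cell classes apart, with the line as the unit. Photoreceptor lines were set apart by genes that rods and cones share. Rcvrn, the calcium sensor recoverin, averaged 1270 intensity units in the 3 photoreceptor lines (SD 0.37 on the log2 scale, n = 3) and at most 2.66 in any of the other 19 lines. The difference was at least 8.27 log2 units (11.43, SE 1.17, without the floor; adjusted p = 4.4e-06). Guca1a, an activator of photoreceptor guanylate cyclase, was at least 7.85 units higher, Sag, the arrestin that quenches rhodopsin, at least 7.56, and Pde6g, a phosphodiesterase subunit, at least 6.28. Outside phototransduction, Vtn, which encodes vitronectin, was at least 7.43 units higher and Krt18, a keratin, at least 6.35; Ppm1n, Prcd, Neurod1 and Fabp4 completed the 10 genes that the naming rule takes. Of the 16 measured genes common to rods and cones 13 rose (13 adjusted over the list alone, list adjusted p = 6.9e-18), among them Crx, the photoreceptor homeobox factor, by 3.92 units (SE 0.45), and Tulp1 by 4.35 (SE 0.51). Ribbon synapse genes rose in 5 of 9 cases (5 adjusted over the list alone, list adjusted p = 0.00017), with Cabp4 1.75 units (SE 0.34) and Cacna1f 2.74 units (SE 0.77) higher. Cacna1f did not pass with batch removed as a term (2.13, adjusted p = 0.23). Of 12 ganglion cell markers 4 fell (5 adjusted over the list alone), for example Nefm (-1.89, SE 0.46; -1.46 and adjusted p = 0.19 with batch removed). That list's adjusted p of 0.00076 became adjusted p = 0.11 with an estimated correlation. The ganglion class is part of the reference, which by itself lowers its markers in the other classes. In all, 307 genes were higher and 653 lower in photoreceptors. The lines of batch 1 alone gave 216 genes and those of batch 2 alone 0 in limma (1812 at an unadjusted p under 0.05), and batch 3 holds no photoreceptor line. With batch removed Sag (4.36, adjusted p = 0.48), Guca1a (8.30, adjusted p = 0.12), Vtn (7.50, adjusted p = 0.16), Neurod1 (7.64, adjusted p = 0.06) and Fabp4 (9.46, adjusted p = 0.52) no longer passed. That fit left out d4, so b2 and Chrnb4 alone stood for the class. The batch shift it removed came from the Arc and b2 sets, and Sag differed by 8.46 between the 2nd and 3rd Arc sets. These lost calls therefore do not show that batch caused the differences.

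The horizontal cell line Gja10 stood apart by genes known from horizontal cells. Calb1, the calcium buffer calbindin, reached 595 intensity units against 14.7 in the mean of the other 21 lines. Against the mean of the other classes it was 5.70 log2 units higher (SE 1.13, n = 1 line against 21; adjusted p = 0.01). Lhx1, a LIM homeobox factor that places horizontal cells in their layer, was 4.13 units higher (SE 0.21), and its highest other line reached 8.62 intensity units against 102. Of the 6 measured horizontal cell markers 4 rose (6 adjusted over the list alone, list adjusted p = 7.6e-16), with Septin4 at 4.30 (SE 0.63) and Megf11 at 1.27 (SE 0.31). Tecrl (5.65, SE 0.33), Mtarc1 (4.93, SE 0.20), Wfdc10, Vim, Nebl, Ndrg1 and Gm16551 were also higher than in every other line. Among 9 genes of the conventional synapse, 2 rose (2 adjusted over the list alone), Snap25 by 2.43 (SE 0.49) and Syt2 by 1.99 (SE 0.21); that list's adjusted p of 0.034 became adjusted p = 0.23 with an estimated correlation. The comparison called 158 genes higher and 24 lower, 152 in all among the lines of batch 3 alone. Since the class holds 1 line, its spread between lines was taken from the other classes. With batch removed as a term Vim (4.83, adjusted p = 0.07) and Snap25 (2.13, adjusted p = 0.052) no longer passed, nor did Megf11 without the filter on dim genes (1.27, adjusted p = 0.054).

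Bipolar lines shared markers of their class and genes of the cascade by which ON bipolar cells answer glutamate. Scgn, the calcium-binding protein secretagogin, was 5.33 log2 units higher than in the other classes (SE 0.73, n = 4 lines against 18; adjusted p = 0.00024), Cabp5 4.97 (SE 0.69) and the G protein subunit Gng13 4.88 (SE 0.64). Otx2, a homeobox factor of bipolar cells and photoreceptors, was 4.57 units higher (SE 0.42), with its highest other line, the cone line d4, at 107 intensity units against 226. Of 7 bipolar markers 5 rose (6 adjusted over the list alone, list adjusted p = 5.4e-15). Of 11 genes of the ON cascade 8 rose (8 adjusted over the list alone, list adjusted p = 1.7e-18), including Trpm1, the transduction channel, by 2.94 (SE 0.40) and Gnao1, the G protein that gates it, by 2.39 (SE 0.26). Ribbon synapse genes rose in 3 of 9 cases (6 adjusted over the list alone, list adjusted p = 2.1e-06), Cacna2d4 by 2.44 (SE 0.27). Of 14 calcium-binding protein genes 3 rose (6 adjusted over the list alone, 3 of them higher), while the list as a whole did not shift (adjusted p = 0.51). The GABA-C receptor subunits Gabrr1 and Gabrr2 were 3.71 (SE 0.47) and 4.23 (SE 0.41) units higher. Pcp2, Tmem215, Lrtm1, Nrn1l and the small nuclear RNA gene Rnu12 completed the named genes. Of 12 ganglion cell markers 4 fell and 1 rose (6 adjusted over the list alone, list adjusted p = 0.00014, adjusted p = 0.078 with an estimated correlation). The 1 that rose, Isl1 (4.32, SE 0.80), is also a factor of ON bipolar cells. As the ganglion class is part of the reference, falls of its markers are in part set by the reference. In all, 229 genes were higher and 173 lower. Leaving out the microglia line Csf2rb2 gave 260 genes in place of 402, and the lines of batch 1, 2 and 3 alone gave 32, 0 (limma; 1191 at an unadjusted p under 0.05) and 577.

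Amacrine lines shared inhibitory transmitter genes. Slc32a1, the vesicular transporter that loads GABA and glycine, averaged 477 intensity units in the 9 lines (SD 0.21 on the log2 scale, n = 9). It was 2.34 log2 units higher than in the other classes (SE 0.28; adjusted p = 2.6e-05), with its highest other line, the horizontal line Gja10, at 290. Of 11 amacrine markers 6 rose (7 adjusted over the list alone, list adjusted p = 1e-09), among them Pax6, a homeobox factor, by 2.62 (SE 0.29) and Tfap2a by 1.19 (SE 0.28; adjusted p = 0.085 with batch removed). Of 4 GABA and glycine release genes 3 rose (4 adjusted over the list alone, list adjusted p = 1.8e-05): Slc32a1 and the GABA-synthesizing enzymes Gad1 (1.98, SE 0.46) and Gad2 (1.99, SE 0.45). Beside these, 14 of 18 microglia markers fell (15 adjusted over the list alone, list adjusted p = 2.2e-20, adjusted p = 0.066 with an estimated correlation), Csf1r (-1.30, SE 0.19). Photoreceptor genes common to rods and cones fell in 3 of 16 cases (4 adjusted over the list alone, list adjusted p = 3.5e-05, adjusted p = 0.081 with an estimated correlation). The microglia and photoreceptor classes are part of the reference, which by itself lowers their markers in the amacrine class. Csf1r, for example, stood at 444 intensity units in the microglia line against a median of 7.68 over the lines. Only Slc32a1 and Tmem191c (1.51, SE 0.18) lay above every line of the other classes among the 234 genes higher; 185 were lower. Leaving out the microglia line Csf2rb2 gave 169 genes in place of 419, and the lines of batch 1, 2 and 3 alone gave 26, 0 (limma; 1172 at an unadjusted p under 0.05) and 458.

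Ganglion cell lines were set apart by markers of their class. Sncg, gamma-synuclein, reached a mean of 1450 intensity units and was 5.02 log2 units higher than in the other classes (SE 0.32, n = 4 lines against 18; adjusted p = 4.1e-09). Nefl, the light neurofilament chain, was 4.14 units higher (SE 0.47), Nrn1, the neurite growth factor neuritin, 4.60 (SE 0.19), S100a10 4.89 (SE 0.40) and Tppp3 4.76 (SE 0.36); Atp6ap1l, Lgals1, Fbxo2, Uchl1 and 2900055J20Rik completed the 10. Of 12 ganglion cell markers 9 rose (9 adjusted over the list alone, list adjusted p = 1e-16), including Rbpms by 3.56 (SE 0.21), the glutamate transporter gene Slc17a6 by 2.58 (SE 0.21) and the POU factor Pou4f1 by 1.98 (SE 0.22). Of 17 neuropeptide genes 3 rose (4 adjusted over the list alone, list adjusted p = 0.039, adjusted p = 0.14 with an estimated correlation): Gal by 1.77 (SE 0.24), Nppb by 1.65 (SE 0.45) and Adcyap1 by 1.63 (SE 0.32). The latter 2 rest mainly on the Opn4 line, at 188 and 78.7 intensity units against at most 18.6 and 17.8 in the other ganglion lines. Of 14 calcium-binding protein genes 3 rose (3 adjusted over the list alone), Calb2 by 5.33 (SE 1.07), Necab2 by 3.65 (SE 0.48) and Pvalb by 3.50 (SE 0.65), while the list as a whole did not shift (adjusted p = 0.065). Genes of other cell types moved with this class: 3 of 9 endothelial markers rose (3 adjusted over the list alone, list adjusted p = 0.0032, adjusted p = 0.3 with an estimated correlation), Cldn5 by 3.09 (SE 0.80; -0.20 among the lines of batch 1 alone), highest in Grik4 at 681 intensity units and Drd4 at 232. Of 9 markers of the retinal pigment epithelium 1 rose, Ttr, by 3.21 (SE 0.69; -0.19 in batch 1 alone), with 3 adjusted over the list alone and a list adjusted p = 0.028, or adjusted p = 0.31 with an estimated correlation. In all, 492 genes were higher and 147 lower; leaving out Gja10, PV or Drd4 gave 977, 1051 and 411 genes in place of 639, and the lines of batch 1 and batch 3 alone 60 and 409.

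The microglia line Csf2rb2 showed the immune profile of that cell. This class too holds 1 line, so its spread between lines was taken from the other classes. Ccl3, a chemokine, reached 1480 intensity units against 12.5 in its highest other line, 8.16 log2 units above the other classes (SE 0.46, n = 1 line against 21; adjusted p = 1.4e-10). C1qc, a complement subunit, was 7.54 units higher (SE 1.11). All 18 measured microglia markers rose (18 adjusted over the list alone, list adjusted p = 7.7e-32), for example the receptor genes Csf1r by 5.71 (SE 0.41) and Cx3cr1 by 5.96 (SE 0.94). Of 19 complement and innate immunity genes 16 rose and 1, the properdin gene Cfp, fell (-1.41, SE 0.40; 18 adjusted over the list alone, list adjusted p = 3.1e-31). All 5 antigen presentation genes rose (5 adjusted over the list alone, list adjusted p = 5.8e-07), H2-Ab1 by 5.06 (SE 0.57). Of 8 listed monocyte or perivascular macrophage markers 7 were in the table and 3 were tested. These 3 rose (3 adjusted over the list alone, list adjusted p = 2.5e-06), Lyz2 by 5.37 (SE 0.49). Ccr2, Ly6c2, Mrc1, Cd163 and F13a1 were not tested. Those of them in the table were left out as dim, with no set above 9.01, the microglia set included. The rise of the 3 therefore does not stand for the whole list. Immediate early and dissociation stress genes rose in 4 of 15 cases (4 adjusted over the list alone, list adjusted p = 0.044, adjusted p = 0.34 with an estimated correlation), Atf3 by 2.53 (SE 0.22). The remaining named genes, Tyrobp, Tlr1, Ctss, Gpr65, Cd48, C1qb, Cd14 and Tmem273, lay between 6.92 and 7.12 units higher. In each of them the ganglion cell line Grik4 was the highest other line, Ctss reaching 489 intensity units there against 2640 in microglia. The comparison called 858 genes higher and 549 lower, 1756 in all among the lines of batch 3 alone.

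**Figure D1:**
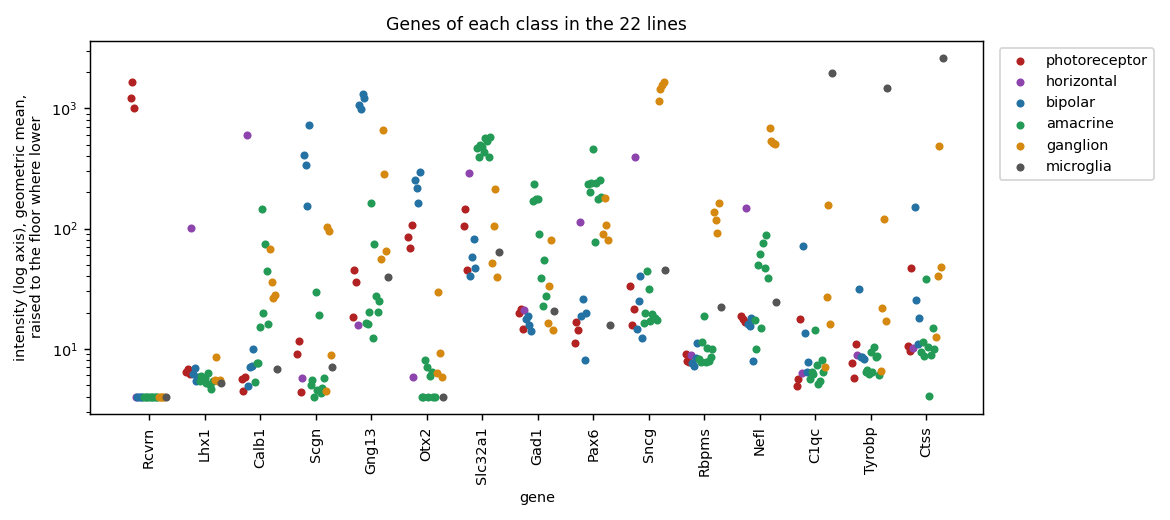
Intensity (log axis, geometric mean of each line, raised to the floor of 3.99 where lower) of 15 genes of the 6 classes, 1 point per line coloured by class. Rcvrn is at 1010 or more in the 3 photoreceptor lines and at the floor elsewhere, and Slc32a1 lies between 391 and 575 in the 9 amacrine lines.

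**Figure D2:**
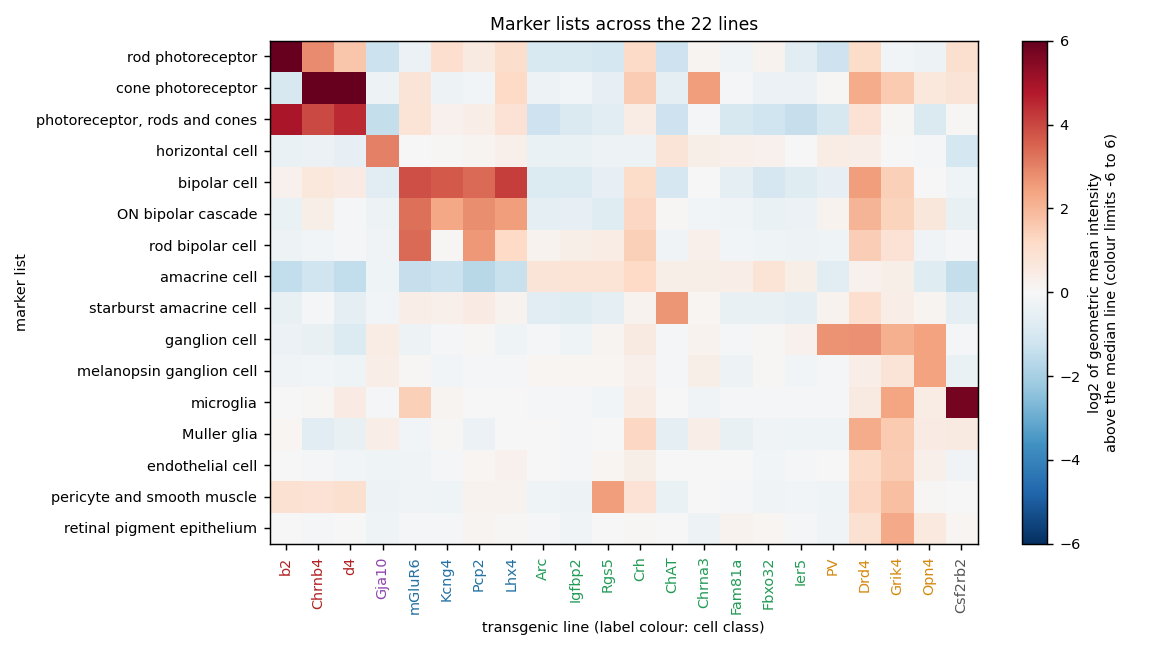
Geometric mean intensity of 16 marker lists in the 22 lines, as log2 above the median line of each list (colour limits -6 to 6). The rod list peaks in b2 (7.15) and the microglia list in Csf2rb2 (5.72), followed by Grik4 (2.39).

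Of 397 transcription factor genes tested (the naming patterns also take in Arxes1 and Arxes2, which are not such factors), 25 were higher in microglia, 15 in bipolar, 13 in ganglion, 10 in amacrine, 8 in photoreceptor and 2 in horizontal cells. Arxes1 and Arxes2 are both inside the bipolar, ganglion, amacrine and photoreceptor counts, which thus hold fewer factors. The counts for pairs of lines below use the same patterns. Spi1, the myeloid master factor, was 3.66 log2 units higher in microglia (SE 0.25), Pou3f2 2.79 in ganglion cells (SE 0.37) and Rax, a photoreceptor homeobox factor, at least 4.74 in photoreceptors. Single lines exceeded the next line by over 1 log2 unit for Nrl in b2 (2.25), Sox2 in the starburst line ChAT (1.98), Eomes in Opn4 (1.51), Bhlhe23 in mGluR6 (1.29), Fezf2 in Igfbp2 (1.18) and Neurod6 in Chrna3 (2.18). These were picked after their values were seen. Any pair of the 231 pairs of lines differed in at least 2 factors, with a median of 35; the median was 18 for lines of the same class and 37 for lines of different classes. The part of batch in these counts was not tested, and they rest on the spread between the arrays of a set. Over all genes, the median pair differed in 1263 genes, from 54 (Arc and Igfbp2) to 6060. By the same fit, repeated sets of 1 line differed in 8 to 314 genes, the factor Cebpd among them in b2 (1.81, 1st against 2nd). Pairs of lines with low counts lie in that range, so their differences need not set the lines apart.

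Genes of 6 retinal diseases were tested in each class. Of 35 measured retinitis pigmentosa genes 12 rose in photoreceptors (12 adjusted over the list alone), Fam161a by at least 5.21 log2 units and Rbp3 by at least 5.53. The list's adjusted p of 1.6e-05 became adjusted p = 0.15 with an estimated correlation. Of 14 genes of Leber congenital amaurosis 9 rose (9 adjusted over the list alone, list adjusted p = 1.4e-12), Rd3 by 3.48 (SE 0.46). Of 11 genes of cone dystrophy and achromatopsia 6 rose (7 adjusted over the list alone, list adjusted p = 4.3e-07), Cngb3 by 3.03 (SE 0.71). Genes of congenital stationary night blindness rose in photoreceptors in 3 of 9 cases (3 adjusted over the list alone), where the list did not shift (adjusted p = 0.22). In bipolar cells 2 rose (3 adjusted over the list alone) and the list shifted (adjusted p = 0.00061, adjusted p = 0.023 with an estimated correlation). These were Cabp4, Cacna1f and Grk1 (1.76, SE 0.34) in the former, and Grm6 (1.49, SE 0.39; adjusted p = 0.062 with batch removed) and Trpm1 in the latter. Of 12 genes of age-related macular degeneration 3 rose in microglia (4 adjusted over the list alone), Apoe by 4.20 (SE 0.89), Cx3cr1 and Tlr4 (2.27, SE 0.26), and 1, the growth factor gene Vegfa, fell (-1.18, SE 0.30); the list did not shift (adjusted p = 0.13). Of 10 genes of glaucoma and optic neuropathy 1 rose in any class, Six6 in amacrine cells (1.70, SE 0.40), where the list did not shift (adjusted p = 0.89).

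The driver comparison asks whether the gene whose promoter or locus drives the reporter is highest in its own line. It passed for 17 of 20 genes (17 adjusted over the list alone), and 17 genes had their own line ranked first of 22. Crh, the stress peptide corticotropin-releasing hormone, reached 307 intensity units in its line against 14.0 in the next (6.13 log2 units above the mean of the other lines, SE 0.41, n = 3 arrays). Chrna3, a nicotinic receptor subunit, reached 590 against 31.8 (5.78, SE 0.26), and Opn4, the photopigment melanopsin, 149 against 13.8 (4.09, SE 0.20). Igfbp2 was 5.75 units higher in its line (SE 0.50) and Pvalb 5.32 in the line PV (SE 0.31). Chrnb4 passed in the cone line named after it (1.45, SE 0.17) at 24.3 intensity units, although the amacrine line Chrna3 reached 60.8. Chat, the acetylcholine-synthesizing enzyme, was 0.40 units higher in the ChAT line (SE 0.13; adjusted p = 0.059 over all genes and 0.0029 adjusted over the list alone), below the size asked for. The Grik4 gene was at 7.05 intensity units in the Grik4 line (-0.23, SE 0.13; adjusted p = 0.27) and the Drd4 gene at 2.23, below the floor, in the Drd4 line, whose labels name EGFP in the line and RFP in the description (-0.25, SE 1.37; adjusted p = 0.91). The highest line of the Drd4 gene was the rod line b2 at 645, and its difference turned to 2.40 with batch as a term (adjusted p = 0.32). Its probe set lay in the ordered runs of lowest values on 42 of the 63 arrays outside the photoreceptor class. Its low value in the Drd4 line can therefore not be read as absence of the transcript.

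**Figure D3:**
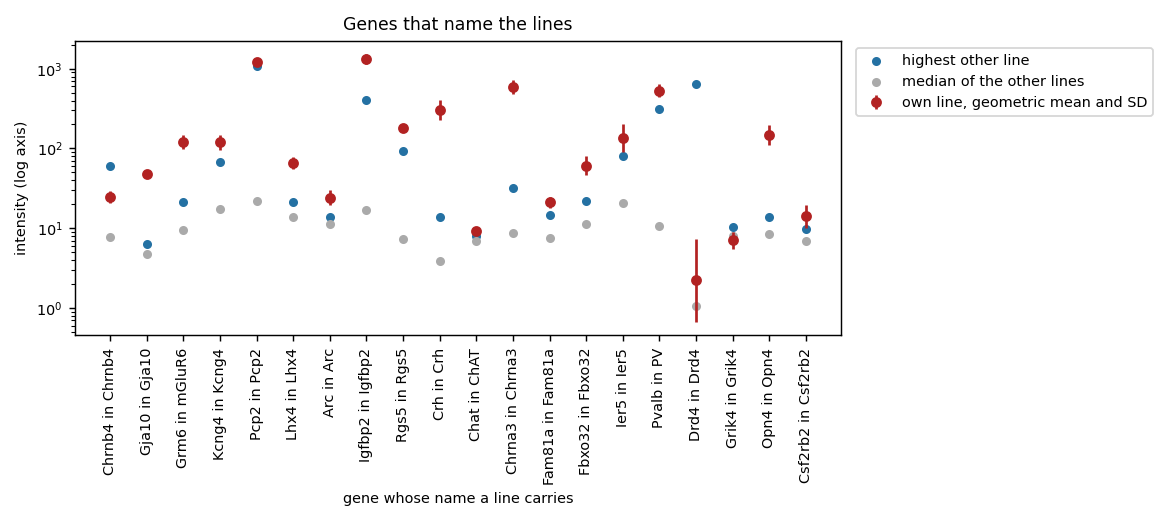
Intensity (log axis) of the 20 genes that name a line: geometric mean of the own line with its SD (3 arrays, 9 for Arc), the highest other line and the median of the other lines. Own-line points lie highest in 17 genes, and the gene Drd4 peaks at 645 in the line b2.

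The contrast of rods with cones compares the 9 arrays of b2 with the 6 of the cone lines Chrnb4 and d4. Rods were higher in the rod form of the transduction cascade: Gnat1, rod transducin, at least 6.93 log2 units (10.43, SE 1.30, without the floor, n = 9 and 6 arrays; adjusted p = 6.5e-09). Pde6b, a rod phosphodiesterase, was higher by at least 7.77, Cnga1, a channel subunit, at least 6.99, and Gnb1 at least 8.38. Cones were higher in Opn1sw and Opn1mw, the short- and middle-wavelength opsins, with b2 lower by -9.20 and -8.97 or more, in Arr3, the cone arrestin (-8.32 or more), and in Gnat2, cone transducin (-9.07 or more). Of 11 rod genes 8 rose (8 adjusted over the list alone, list adjusted p = 4.2e-12) and of 11 cone genes 10 fell (10 adjusted over the list alone, list adjusted p = 4.7e-25). The rod factor Nrl was 3.25 units higher (SE 0.44) and Rxrg, a nuclear receptor of cones, lower, at -4.36 (SE 0.22). Other named genes higher in rods were Lmo1, Dhrs3, Sap30, Sh2d1a and the olfactory receptor genes Olfr39 and Olfr881, and in cones Pde6c, Pde6h, Gngt2, Kcne2, Scg3 and Olfr1372-ps1. Of 11 cone dystrophy and achromatopsia genes 4 fell (4 adjusted over the list alone), Cngb3 (-4.54 or more), Gnat2, Pde6c and Pde6h. The list's test was down (adjusted p = 0.0048) with a mean of -3.30 and a median of 0.01. Beside these, the Müller glia genes Glul and Rlbp1 were at least 3.94 and 2.73 units higher in rods. In all 709 genes were higher and 909 lower. With batch as a term 1220 genes passed, 904 of them shared, but Opn1sw did not (-16.32, adjusted p = 0.063), and within batch 1 alone b2 against Chrnb4 gave 124 genes.

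**Figure D4:**
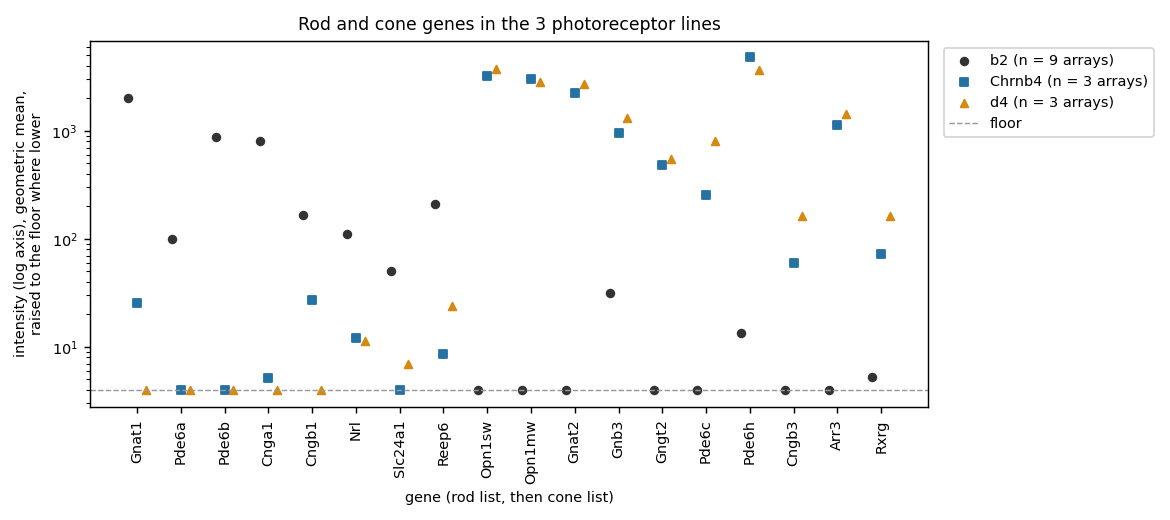
Intensity (log axis, geometric mean, raised to the floor where lower) of 8 rod and 10 cone genes in the rod line b2 (9 arrays) and the cone lines Chrnb4 and d4 (3 arrays each). The 8 rod genes are highest in b2 and the 10 cone genes highest in the cone lines.

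Between the cone lines, Chrnb4 and d4, the contrast asks whether lines of 1 labelled type differ. Mt1, which encodes a metallothionein, was at 3370 intensity units in d4 and below the floor in Chrnb4, a difference of -9.72 log2 units or more (-12.50, SE 1.25, without the floor, n = 3 and 3 arrays; adjusted p = 5.6e-10). Kcna5, a potassium channel gene, was 4.37 units higher in Chrnb4 (SE 0.47) and Strbp at least 5.42 higher. The rod gene Gnat1 was called higher in Chrnb4 at 25.4 intensity units, but with an SD of 5.96 on the log2 scale, since 1 of its 3 arrays lay below the floor, so no size is given. The differences of Mt2 (1.10, adjusted p = 0.36) and Defb5 (1.53, adjusted p = 0.3) did not pass with the floor. Of 11 cone genes 2 were lower in Chrnb4, Cngb3 (-1.46, SE 0.39) and Rxrg (-1.18, SE 0.35). Neither passed with batch as a term and d4 taken as batch 2 (-1.52, adjusted p = 0.11; -0.94, adjusted p = 0.32). The other named genes were Gm5878, Gm7982, Trps1, Gm10139 and BC018473, higher in Chrnb4, and Tra2b, Armcx3, Exosc7, Prim1, 1110059G10Rik, Psmd7, Polr2d, Wdfy3 and Bbs7, lower. Of the 759 genes called (361 to 653 with 1 replicate number left out of every set), 191 were higher and 568 lower. No batch is given for d4; taking it as batch 2 gave 245 genes with batch as a term.

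Each bipolar line was set against the other 3. The mGluR6 line, labelled ON-bipolar, was higher in markers of rod bipolar cells. Of the 6 measured, 6 rose (6 adjusted over the list alone, list adjusted p = 7.1e-23), Prkca, a protein kinase C, by 2.04 (SE 0.24, n = 3 and 9 arrays) and Car8 by 2.57 (SE 0.40). Cck, the peptide cholecystokinin, was 4.61 units higher (SE 0.67), Pcp4l1 3.25 (SE 0.46), Kcne2 at least 4.17, and Nrm and Me1 were the other named genes. With batch as a term Nrm (2.31, adjusted p = 0.39) and Me1 (2.79, adjusted p = 0.18) no longer passed. Of 11 ON cascade genes 4 rose (4 adjusted over the list alone, list adjusted p = 2.8e-05, adjusted p = 0.15 with an estimated correlation), Grm6, the glutamate receptor that names the line, by 2.82 (SE 0.19). Microglia markers rose beside them in 10 of 18 cases (11 adjusted over the list alone, list adjusted p = 3.1e-18), C1qc by 3.03 (SE 0.47). The count of 387 genes was 193 without mGluR6 replicate 1 and 238 with batch as a term. In the Kcng4 line 5 of the 6 rod bipolar markers fell (5 adjusted over the list alone, list adjusted p = 1e-39), Car8 (-4.06, SE 0.40) and Prkca (-1.92, SE 0.24). Wfdc1, a secreted protease inhibitor, was higher at 890 intensity units against 27.9 in the mean of the others, and the adhesion gene Cdh9 was 1.45 units higher (SE 0.25). Gckr and Enkd1 were higher too (at least 2.94; 2.87, SE 0.70, but adjusted p = 0.14 with batch as a term); Rax and Olfr901 did not pass with the floor (1.49, adjusted p = 0.23; 1.91, adjusted p = 0.11). The count of 127 genes was 84 without Kcng4 replicate 1 and 66 without replicate 2.

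The Pcp2 line, labelled rod bipolar, had 4 of the 6 rod bipolar markers higher and 1, Bhlhe23, lower (-1.05, SE 0.20; adjusted p = 0.12 with batch as a term; 5 adjusted over the list alone, list adjusted p = 5.1e-05). Sebox was 2.23 units higher (SE 0.21) and Car8 2.16 (SE 0.40). Cdh9 was lower (-2.30, SE 0.25). Its 5 named genes, Gm10139, Olfr202, A530040E14Rik, Rep15 and Krtap5-1, lay at least 3.04 to 4.50 units higher, and none passed with batch as a term (lowest adjusted p = 0.36). The count of 430 genes was 53 with batch as a term, and 232, 274 and 286 without Pcp2 replicate 1, 2 and 3. In the Lhx4 line the homeobox gene Lhx4 was 1.90 units higher (SE 0.20), Grik1, a kainate receptor subunit of OFF bipolar cells, 1.90 (SE 0.32), Nfib 3.97 (SE 0.53), Otor 4.52 (SE 0.48), Ackr3 4.52 (SE 0.48) and 6330403K07Rik 4.22 (SE 0.47). Prkca and Sebox, 2 of the 6 rod bipolar markers, fell (-1.79, SE 0.24, and -1.47, SE 0.21; 2 adjusted over the list alone, list adjusted p = 0.00016, adjusted p = 0.063 with an estimated correlation). The cone gene Opn1sw was at least 4.70 and the rod gene Gnat1 at least 3.93 units higher there; neither passed with batch as a term (9.76, adjusted p = 0.59; 5.21, adjusted p = 0.26). The count of 421 genes was 153 with batch as a term, 166 without Lhx4 replicate 1 and 817 without replicate 3.

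Amacrine lines were each set against the other 8. The Arc line was higher in Cartpt, the peptide CART, by 3.91 (SE 0.37, n = 9 and 24 arrays; adjusted p = 3.6e-12) and in Vip, vasoactive intestinal peptide, by 3.10 (SE 0.17). That of Vip is the mean of a 1st set at 4.67 intensity units and of 2 later sets at 208 and 224. Of its named genes Wfikkn2 rose by 3.25 (SE 0.23), with Cmbl, Marcks and Syt10 after it. Th, the rate-limiting enzyme of dopamine synthesis, was 1.39 units higher (SE 0.20), 1 of 4 dopamine release genes (1 adjusted over the list alone, list adjusted p = 0.015). Calcium-binding protein genes fell in 3 of 14 cases (3 adjusted over the list alone, list adjusted p = 9.2e-15), Calb2 (-3.74, SE 0.20), Calb1 (-2.21, SE 0.19) and Hpca (-1.96, SE 0.19); 187 genes passed. The Igfbp2 line was higher in Igfbp2 (5.27, SE 0.52), the amino acid transporter gene Slc38a5 (4.30, SE 0.17), C1ql3 (3.95, SE 0.47), Lgals1 and Pla2g7 (at least 3.22). The peptide genes Npy (3.80, SE 0.60) and Vip (3.11, SE 0.27) were higher as well but did not pass with batch as a term (Npy 1.78, adjusted p = 0.87, and Vip 0.80). Arc was the only line measured in batch 3 and in another batch, and its Vip and Npy rose after its 1st set. That rise enters the batch term. Rgs5 and Crh, also of batch 3, had Vip at 5.09 and 5.69 intensity units against 60.5 in Igfbp2. Their Npy was at 32.7 and 86.9 against 1070. The lost calls can therefore not be read as a batch difference. Calcium-binding genes fell in 4 of 14 cases (4 adjusted over the list alone, list adjusted p = 4.5e-07), Calb2 again (-3.74, SE 0.31). Its count of 218 genes was 144 without Igfbp2 replicate 2 and 129 with batch as a term.

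The Rgs5 line carried contractile genes of pericytes and smooth muscle beside amacrine genes. Of 11 pericyte and smooth muscle markers 7 rose (7 adjusted over the list alone, list adjusted p = 2.1e-40), Higd1b by 4.30 (SE 0.24, n = 3 and 30 arrays), Rgs5 by 4.28 (SE 0.31) and the smooth muscle actin gene Acta2 by 4.08 (SE 0.38). Mgp was 4.10 units higher (SE 0.33) and Apela, a peptide ligand of the apelin receptor, at least 5.41. Gad2 (2.14, SE 0.28) and the enkephalin gene Penk (2.22, SE 0.46) were higher, and 5 of 14 calcium-binding genes fell (5 adjusted over the list alone, list adjusted p = 2.2e-11), Calb2 (-2.81, SE 0.31). The 117 genes called were 76 without Rgs5 replicate 2. In the Crh line, Crh was 5.94 units higher (SE 0.42), Slitrk6 5.43 (SE 0.53), Gdpd3 4.45 (SE 0.54), Ctxn2 4.17 (SE 0.39) and Calb2 4.07 (SE 0.31). The rod gene Gnat1 was at least 7.06 units higher, but Pde6b lay below the floor. The rod list did not shift as a whole (4 of 11 higher and 2 lower, 6 adjusted over the list alone; adjusted p = 0.59). Of 7 bipolar markers 4 rose (4 adjusted over the list alone, list adjusted p = 0.019, adjusted p = 0.33 with an estimated correlation), Pcp2 by 3.41 (SE 0.43). Of 11 ON cascade genes 7 rose (7 adjusted over the list alone, list adjusted p = 7e-05, adjusted p = 0.17 with an estimated correlation). This set had the lowest correlation between its arrays (0.7), and its 2769 genes (959 higher, 1810 lower) became 4353 without Crh replicate 1 and 1576 without replicate 2.

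The ChAT line, labelled starburst amacrine, was higher in Slc18a3, the vesicular acetylcholine transporter, by 6.87 (SE 0.31, n = 3 and 30 arrays; adjusted p = 8e-26). It was also higher in Slc10a4, a vesicular protein of cholinergic neurons, by 5.27 (SE 0.43), and in the factors Isl1 (5.19, SE 0.44) and Sox2 (4.02, SE 0.30). Of 6 starburst markers 3 rose (3 adjusted over the list alone, list adjusted p = 2.4e-23). Calcium-binding genes rose in 5 of 14 cases and fell in 2 (7 adjusted over the list alone, list adjusted p = 0.00069), Hpcal1 rising by 4.99 (SE 0.61) and Calb2 by 4.25 (SE 0.31). Cmtm8 was 5.15 units higher (SE 0.39), Cck 3.99 (SE 0.61) and Npy 4.02 (SE 0.60). The GABA enzyme Gad2 was lower (-2.50, SE 0.28) and the glycine transporter Slc6a9 (-1.88, SE 0.30), 2 of 4 release genes (2 adjusted over the list alone, list adjusted p = 0.0014); 418 genes passed. The Chrna3 line was higher in the nicotinic receptor genes Chrna3 (5.92, SE 0.27) and Chrna5 (5.97, SE 0.26), in Neurod6, a bHLH factor (5.06, SE 0.38), and in the somatostatin gene Sst (2.80, SE 0.19). The cone genes Pde6h and Opn1mw were at least 6.71 and 6.09 units higher, though Opn1mw did not pass with batch as a term (7.11, adjusted p = 0.13). The cone list did not shift as a whole (4 of 11 higher and 2 lower, 6 adjusted over the list alone; adjusted p = 0.67). Stress and immediate early genes rose in 4 of 15 cases (4 adjusted over the list alone, list adjusted p = 0.013, adjusted p = 0.14 with an estimated correlation), Btg2 by 1.84 (SE 0.39). The 1189 genes became 753 without Chrna3 replicate 1 and 724 with batch as a term.

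Fam81a, Fbxo32 and Ier5 cells shared a rise of Slc6a9, the glycine transporter GlyT1. It was 2.63 units higher in Fam81a (SE 0.30, n = 3 and 30 arrays), 2.99 in Fbxo32 (SE 0.30) and 1.16 in Ier5 (SE 0.30); Slc6a5, the other glycine transporter, was not tested. Gad1 was lower in Fam81a (-2.07, SE 0.23) and Ier5 (-1.76, SE 0.23). Calcium-binding protein genes rose in 2, 2 and 3 of 14 cases (2, 3 and 4 adjusted over the list alone): Calb1 in Fam81a (2.07, SE 0.30) and Fbxo32 (1.23, SE 0.30), Hpca (1.98, SE 0.29), Calb2 and Cabp1 in Ier5. These lists' adjusted p were 0.028, 0.00054 and 0.0015, and for Fam81a adjusted p = 0.051 with an estimated correlation. In Fam81a, Actc1, cardiac actin, was 4.76 units higher (SE 0.38), Spink13 4.76 (SE 0.41), Ptgds 2.45 (SE 0.38) and Ppp1r1a 1.94 (SE 0.27), while Ptp4a3 did not pass with batch as a term (1.84, adjusted p = 0.24). In Fbxo32, Myf6, a muscle bHLH factor, was 3.24 units higher (SE 0.28), Bpifa2 2.92 (SE 0.23), Htra1 2.83 (SE 0.71), Wdyhv1 2.09 (SE 0.27) and Il10rb 2.00 (SE 0.24). In Ier5, Gdf3 was 1.68 units higher (SE 0.32), and Thy1 (1.24, adjusted p = 0.28), Dip2c (1.27, adjusted p = 0.39) and 9430038I01Rik (1.23, adjusted p = 0.56) did not pass with batch as a term. Genes called were 229 in Fam81a (133, 136 and 137 without Fam81a replicate 1, 2 and 3; 113 with batch as a term). They were 127 in Fbxo32 (73 without Fbxo32 replicate 2; no batch given) and 279 in Ier5 (144 without Ier5 replicate 2; 130 with batch as a term).

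Ganglion cell lines were each set against the other 3. Opn4 cells, labelled melanopsin ganglion cells, were higher in Opn4 itself by 4.02 (SE 0.23, n = 3 and 9 arrays; adjusted p = 1.3e-20). Also higher were Eomes, a T-box factor of these cells, by 2.94 (SE 0.23), and Adcyap1, the peptide PACAP, by 2.45 (SE 0.19). Of 7 melanopsin cell markers 4 rose (5 adjusted over the list alone, list adjusted p = 4.7e-41). Of 17 neuropeptide genes 3 rose (5 adjusted over the list alone, list adjusted p = 0.02), Nppb, a natriuretic peptide, by 3.65 (SE 0.28). Cdkn1c (4.51, SE 0.68), Cd24a (3.78, SE 0.48) and Prph, the intermediate filament peripherin, (3.33, SE 0.23) were higher; 102 genes passed, 58 without Opn4 replicate 2 and 57 without replicate 3. PV cells were higher in Pvalb, parvalbumin, by 3.14 (SE 0.35) and in Mt1 by at least 6.39, and lower in markers of other cells. Of 18 microglia markers 8 fell (9 adjusted over the list alone, list adjusted p = 2.4e-10), and of 12 Müller glia markers 7 (7 adjusted over the list alone, list adjusted p = 4.6e-06). Falls were also called in 5 of 9 pigment epithelium markers (5 adjusted over the list alone, list adjusted p = 6.8e-06) and 5 of 7 melanopsin cell markers (5 adjusted over the list alone, list adjusted p = 9.4e-10), Eomes (-2.19, SE 0.23). Transcripts abundant in microglia had a median of 16.1 intensity units in PV, 23.8 in Opn4, 43.5 in Drd4 and 116 in Grik4. These falls cannot be told apart from a rise in the lines that PV was set against, the Opn4 line among them. Neurod1 was at least 3.79 units higher in PV, and A530032D15Rik (5.11, adjusted p = 0.11), Ppp3cc (5.48, adjusted p = 0.18) and Olfr1174 (4.35, adjusted p = 0.087) did not pass with batch as a term. The 913 genes called (508 higher) were 83 with batch as a term, 589 without PV replicate 2 and 557 without replicate 3.

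Drd4 cells were higher in Cartpt by 3.86 (SE 0.63, n = 3 and 9 arrays), in Ccl19, a chemokine, by 4.18 (SE 0.62), and in Dapl1 by 3.68 (SE 0.55). Markers of other cells rose beside them. Of 12 Müller glia markers 8 rose (8 adjusted over the list alone, list adjusted p = 1.6e-06), Glul by 2.72 (SE 0.82; adjusted p = 0.068 with batch as a term). Of 7 bipolar markers 4 rose (5 adjusted over the list alone, list adjusted p = 9.1e-07), Cabp5 by 3.40 (SE 0.56), and of the 6 rod bipolar markers 4 (4 adjusted over the list alone, list adjusted p = 3.7e-08). The photoreceptor gene Rbp3 was at least 3.29 units higher, and Cnga1 was called higher too, without a size, as 1 of its 3 arrays lay below the floor. The 958 genes (294 higher) were 237 without Drd4 replicate 1 and 1704 without replicate 3. Grik4 cells were higher in Tmem114, a membrane protein gene, by 5.06 (SE 0.50) and in genes of cells other than neurons. Of 18 microglia markers 14 rose (14 adjusted over the list alone, list adjusted p = 1.8e-48), C1qa by 3.63 (SE 0.43) and Ctss by 4.08 (SE 0.51). Pericyte and smooth muscle markers rose in 5 of 11 cases (5 adjusted over the list alone, list adjusted p = 2.5e-11), and endothelial markers in 3 of 9 (3 adjusted over the list alone, list adjusted p = 6.3e-09). Of 9 pigment epithelium markers 4 rose (6 adjusted over the list alone, list adjusted p = 4.1e-14), Ttr by 4.29 (SE 0.43) and Rpe65 by 3.60 (SE 0.33). Of 11 amacrine markers 4 rose too (4 adjusted over the list alone, list adjusted p = 3e-05), Gad1 by 2.01 (SE 0.25), and Pou4f1 was lower (-1.03, SE 0.24). Cd14 (4.21, SE 0.73) and Ly86 (4.16, SE 0.46) were the other named genes. The 281 genes became 493 without Grik4 replicate 1 and 135 without replicate 2.

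**Figure D5:**
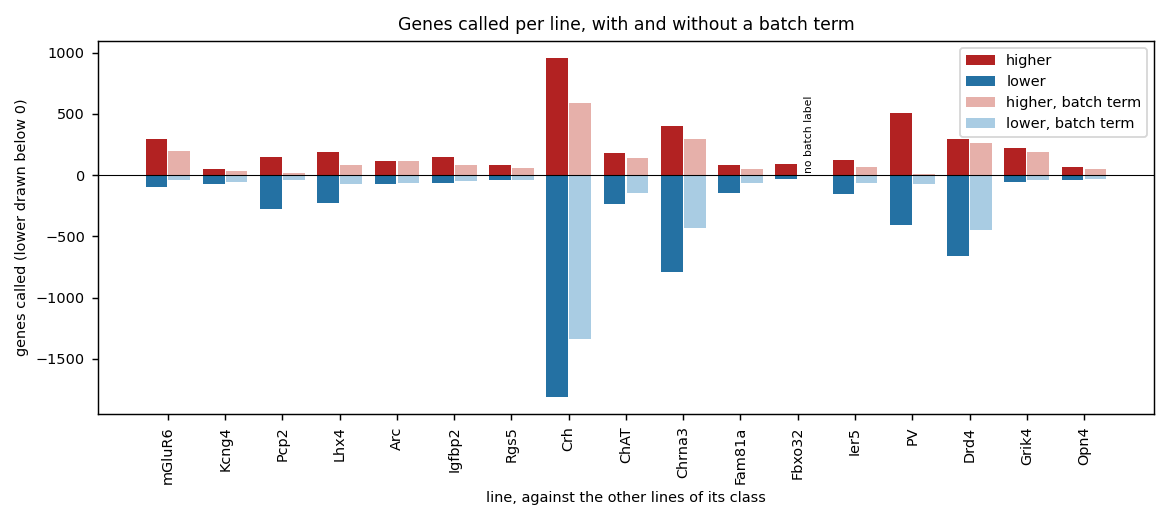
Genes called higher (above 0) and lower (below 0) in each line against the other lines of its class, without and with batch as a term; Fbxo32 has no batch label. The PV count falls from 913 to 83 and the Pcp2 count from 430 to 53.

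The repeated sets show how far the same line differed when measured again. In the Arc line, which the study used as its batch control, Vip was at 4.67 intensity units in the 1st set, 208 in the 2nd and 224 in the 3rd. Npy was at 21.7, 520 and 694, while Cartpt stood at 1460, 1340 and 1510. Cbln4, a synaptic organizer, moved with Vip and Npy, -2.88 log2 units in the 1st set against the 2nd (SE 0.41, n = 3 and 3 arrays; adjusted p = 1.98e-05) and -2.95 against the 3rd (SE 0.41). The 1st and 2nd sets differed in 8 genes, the 1st and 3rd in 69, and the 2nd and 3rd in 11; leaving out 1 replicate number in every set gave 5 to 6, 7 to 21 and 1 to 12. The rod line b2 differed in 314 genes between its 1st and 2nd sets, 179 between the 1st and the unnumbered set and 307 between the 2nd and the unnumbered set. The tubulin gene Tubb2a was lower in the 1st than in the 2nd (-4.34, SE 0.51). Leaving out 1 replicate number gave 120 to 350, 117 to 177 and 106 to 327. The 2nd and unnumbered b2 sets carry the same batch label, so their 307 genes differ within 1 labelled batch. In the other pairs a set and its batch are the same arrays and cannot be told apart. The difference of the 1st set minus the 2nd was not the same in Arc and b2 for 39 genes (27 higher in Arc, 12 lower). Among them were Vip (-5.51, SE 0.50, adjusted p = 2.29e-11), Eif3h (2.48, SE 0.34) and Psmb1 (2.67, SE 0.38). Vip, Npy, Cbln4, Cartpt, Tubb2a, Eif3h and Psmb1 were chosen here after their values were seen.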

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

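The tests of the Arc batch difference in the PV and Pcp2 lines were written before their result was seen; every other test in this part, the splits of the samples included, was chosen after the result was seen.

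In 26 groups of 9 arrays examined for a single distant array, 2 passed the limit, where chance gives about 1 in 20 groups. Sag, the rod arrestin, was at 1960 intensity units in b2 1st replicate 1 against 2470 to 2950 in the other 8 arrays of that line. Lmo1 was at 53.8 in the same array against 168 to 532 in the others. The change between the 1st and 2nd sets differed between the Arc and b2 lines in 39 genes, a difference between groups that was itself tested. Of 100 splits of the arrays, the real one included, 21 gave as many or more, and the highest other split gave 1843 genes. These splits moved arrays between the Arc and b2 lines, which differ in 2317 genes. They thus carry differences between rods and amacrine cells and cannot decide on chance as the source of the count, which is not excluded. Among the 39 genes Vip differed by -5.51 log2 units (adjusted p = 2.29e-11), taken as the 1st set minus the 2nd in Arc, less the same in b2. Vip stood at 4.67 intensity units in the 1st Arc set and 208 in the 2nd.

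The PV and Pcp2 lines, both of batch 1, were set against lines of other batches. Of the 508 genes higher in PV, 89.2% were also higher in the Arc arrays of batch 1 than in those of batch 3, with a median of 0.36 log2 units (0 over all tested genes), and so were 77.5% of the 151 higher in Pcp2 (also 0.36). A batch difference may therefore account for part of these genes, but the medians lie below the 1.54 (median SE 0.40) and 1.42 (median SE 0.36) of the genes themselves. With batch as a term 1.38% of the PV genes (7) and 9.27% of the Pcp2 genes (14) passed, while the median difference was 1.19 (median SE 0.62) and 1.22 (median SE 0.50), so the calls ended mainly as the errors grew. Expression by the cells of each line and the batch cannot be told apart for these genes, since each line was measured in 1 batch.

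The Grik4 and Rgs5 lines carried transcripts of other cells. A lower share of the labelled class with every other cell type up alike is argued against in Rgs5. There the medians of the 17 other lists with the floor spread over 2.44 log2 units, the pericyte list at 2.16 and the other 16 from -0.28 to 0.20. In Grik4 they spread over 2.12 (from -0.24 to 1.88), but 13 lay above 0, as that share would have it. Among these were bipolar at 0.83, Müller glia at 0.66 and amacrine at 0.51. Equal shares of other cells need not give equal log2 shifts, since lists differ in their level. The spread therefore cannot decide for Grik4, and a lower share stays open there. Microglia or their RNA in the sort may explain the microglia genes of Grik4: 86.5% of 74 transcripts abundant in the microglia line (84.7% of the 59 in no gene list) were higher in Grik4 than in the other ganglion lines, at a median excess of 5.46% of the microglia level (quartiles 1.8 and 8.8; 116 intensity units against 16.1 in PV, 43.5 in Drd4 and 23.8 in Opn4). They would not account for the pericyte (1.66), pigment epithelium (1.39) and endothelial (0.48) lists, whose rise in Grik4 stays open, as do pericytes or their RNA, or labelled pericytes, in Rgs5, since the 90.9% of the 11 listed genes that were higher only restate the rise of that list. Expression by the labelled neurons was not tested and stays open.

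The lowest values of an array stand in descending order of probe set identifier, in a run of 10 or more on 70 of the 78 arrays, the longest 2342 probe sets long in the Drd4 line. Tied values ordered upstream of the deposit are a candidate explanation of that order. Dim probe sets at the detection limit stay open: the 16 found in runs on most arrays reach a median of 795 intensity units in their highest set and all 3888 found in a run on any array 60.6, but on other arrays than those of the runs. Photoreceptor signal taken off by the upstream processing stays open for part of these probe sets. Of the 29 in runs on most arrays outside the photoreceptor class, 75.9% peak in photoreceptor lines, Rcvrn, Opn1sw and Gnat1 among them. Of 626 equally bright other probe sets 24.4% do. Choosing probe sets that are lowest outside that class favours such a peak, so these shares cannot decide. If signal was taken off, bounds given against such values would not hold. Among the genes lower in the Crh line, 94.9% were still called with the floor. A value in a run is raised only to the floor, which can still lie below the other amacrine lines. This share therefore cannot decide whether the runs caused these calls, and that stays open.

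For the class comparisons, each taken alone, chance is argued against as the source of the counts in photoreceptor, bipolar, amacrine and ganglion cells. In these 1, 3, 1 and 1 of 100 splits of the lines, the real one included as in every such count here, gave as many genes as the real 960, 402, 419 and 639. The highest other split gave 581, 510, 199 and 492, so another split exceeded the real count in bipolar cells. List shifts between classes numbered 73 against at most 60 in another split, and between lines 124 against at most 78 (1 of 100 in both). For rods against cones it was 1 of 100 (1618 against 815). This test, that of list shifts between lines and those of single lines moved single arrays, although arrays come in sets of 3. A small share then sets off the set with its batch and array quality, and not the line alone. With lines kept whole, rods against cones and single lines have too few splits for a share under 0.05. Chance is therefore not excluded for them. The lines within a class were each taken alone, without adjustment for the 17 lines tested. The share was under 0.05 for mGluR6 (3 of 100, 387 against 500 in the highest other split) and Pcp2 (2 of 100, 430 against 458). It was under 0.05 too for Lhx4 (4 of 100, 421 against 507) and Arc (3 of 100, 187 against 287). The same holds for Crh (1 of 100, 2769 against 552), ChAT (1 of 100, 418 against 391), Chrna3 (2 of 100, 1189 against 1465), PV (3 of 100, 913 against 1407) and Drd4 (1 of 100, 958 against 880). Other splits exceeded the real count in mGluR6, Pcp2, Lhx4, Arc, Chrna3 and PV. The share was 0.05 or more for Kcng4 (6 of 100, 127 against 506) and Igfbp2 (7 of 100, 218 against 1847). So it was for Rgs5 (6 of 100, 117 against 649) and Fam81a (5 of 100, 229 against 1463). Fbxo32 (11 of 100, 127 against 2535) and Ier5 (6 of 100, 279 against 1932) were alike. So were Grik4 (15 of 100, 281 against 1403) and Opn4 (9 of 100, 102 against 1756). In these 8 lines the highest other splits call several times the real count, which points to a structure of the samples. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05, and the real split was the highest in each (1 of 10). It gave 759 against 115 for Chrnb4 and d4. For the Arc sets it gave 8 against 2, 69 against 3 and 11 against 3 (1st and 2nd, 1st and 3rd, 2nd and 3rd). For those of b2 it gave 314 against 204, 179 against 87 and 307 against 202 (1st and 2nd, 1st and unnumbered, 2nd and unnumbered). The horizontal and microglia classes hold 1 line each and were not split.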

How the results depend on the processing

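The floor and the fit without 5 lines were chosen after the data were seen; the other alternatives were planned. Over 101 alternatives 516 of 635 counts stayed within 1.5 times the value reported and 119 did not. One alternative, the pairs of lines within a labelled batch, also took in pairs of different batches, so it is no check of batch. Of 6950 values of named genes 6596 kept direction and call, 347 kept the direction and lost the call, 1 gained it and 6 turned. Quantile-normalizing again moved nothing, as the columns already share identical sorted values, so that setting is void. The lines of batch 2 alone cost 44 of 44 named genes their call and those of batch 1 alone 34 of 67, with 2 more turned, and those of batch 3 alone 14 of 80. Batch as a term cost 25 of 176, or 35 of 206 with d4 and Fbxo32 as batch 2. Leaving out replicate 1, 2 or 3 of every set cost 27, 30 and 23 of 306 and the floor 4 of 306. Except where the construction shows it (fewer lines or arrays), the cause was not tested.

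With 1 replicate, array or line left out, the lone arrays being assumed to vary like the other groups, counts ranged as follows: rods against cones 1374 to 1743, Chrnb4 against d4 361 to 653, mGluR6 171 to 392, Kcng4 40 to 86, Pcp2 172 to 286, Lhx4 166 to 817. Among amacrine lines they were Arc 144 to 203, Igfbp2 110 to 182, Rgs5 56 to 115, Crh 1265 to 4476, ChAT 265 to 383, Chrna3 753 to 1523, Fam81a 84 to 270, Fbxo32 62 to 114, Ier5 88 to 335. Among ganglion lines they were PV 220 to 756, Drd4 237 to 1704, Grik4 87 to 884 and Opn4 31 to 190. For the Arc sets (1st and 2nd, 1st and 3rd, 2nd and 3rd) they were 5 to 6, 7 to 21 and 1 to 12, for the b2 sets 120 to 350, 117 to 177 and 106 to 327, and for the interaction of set and line 20 to 45. For the classes they were 169 to 584 (amacrine), 260 to 496 (bipolar), 411 to 1051 (ganglion), 121 to 226 (horizontal), 1238 to 1567 (microglia) and 708 to 1048 (photoreceptor), and for driver genes 16 to 17.

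With batch as a term the counts were 238 in mGluR6, 53 in Pcp2, 153 in Lhx4, 129 in Igfbp2, 724 in Chrna3, 113 in Fam81a, 130 in Ier5 and 83 in PV. With d4 and Fbxo32 also taken as batch 2 they were 245 in Chrnb4 against d4, 250 in mGluR6, 83 in Kcng4, 57 in Pcp2, 159 in Lhx4, 128 in Igfbp2, 90 in Fam81a, 113 in Ier5 and 94 in PV. Within batch 1, b2 1st against Chrnb4 gave 124. The lines of batch 1 alone gave 26 (amacrine), 32 (bipolar), 60 (ganglion) and 216 (photoreceptor) genes. Those of batch 2 alone gave 0 in limma for amacrine, bipolar and photoreceptor (1172, 1191 and 1812 at an unadjusted p under 0.05), and those of batch 3 alone 409 (ganglion). With the replicate block the class counts were 757 (bipolar), 1183 (ganglion), 860 (horizontal), 2396 (microglia) and 1610 (photoreceptor), and in the fit over all arrays without the block 759, 1185, 861, 2398 and 1611; both take the spread between arrays in place of that between lines.

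Without the 5 lines the counts were 687 in mGluR6, 255 in Kcng4 and 857 in Grik4, 19, 137 and 17 between the Arc sets, 615, 349 and 527 between the b2 sets and 124 in the interaction, which was 59 with the floor. With an estimated correlation 23 of the 73 list shifts between classes and 58 of the 124 between lines passed. The Drd4 gene in its own line, at -0.25, ranged from -1.69 (without replicate 1) to 0.53 (without replicate 2; 0.42 without replicate 3). It turned to 2.40 with batch as a term and 1.86 with d4 and Fbxo32 as batch 2, passing in none. In the ganglion class Cldn5 turned to -0.20 and Ttr to -0.19 among the lines of batch 1 alone.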

Other observations

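Neuropeptide genes were highest in lines of several classes, and some were shared between lines. Tac1, which encodes substance P, was highest in the Crh line at 2480 intensity units and the Igfbp2 line at 2140 against a median of 255, and Npy in ChAT at 1220 and Igfbp2 at 1070 against a median of 30.1. Nppb reached 188 in Opn4 against 18.6 in the next line, Drd4, and Sst 68.7 in Chrna3 against 13.8, also in Drd4. Cck was highest in mGluR6 at 428, followed by ChAT at 288, and the dynorphin gene Pdyn in Chrna3 at 37.5, followed by Crh at 23.7. Gal was highest in Opn4 at 28.4 and Penk in Rgs5 at 45.9, with Drd4 next in both at 17.0 and 40.3.

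In the ganglion class 2 of 12 voltage-gated sodium and potassium channel genes rose (2 adjusted over the list alone, list adjusted p = 0.0068, adjusted p = 0.099 with an estimated correlation), Scn1a by 1.57 (SE 0.31) and Kcnc2 by 1.35 (SE 0.32). Kcnd2 was highest in PV at 47.6 intensity units against 21.6 in the next line, Grik4. The ionotropic GABA and glycine receptor genes rose in 5 of 12 cases in Crh (5 adjusted over the list alone, list adjusted p = 0.0027, adjusted p = 0.12 with an estimated correlation). In PV 3 of 12 fell (3 adjusted over the list alone, list adjusted p = 0.00062, adjusted p = 0.068 with an estimated correlation). Gabra2 was highest in Crh at 27.8 against 12.5 in Arc, and the AMPA receptor gene Gria2 in Crh at 65.5 against 31.0 in Fbxo32. These genes were picked after their values were seen.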
